A study of Mus musculus with 9 samples.

How the data were processed

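Bulk RNA sequencing was analysed from 9 libraries of AML12 cells, a mouse hepatocyte line made from a mouse carrying a transforming growth factor alpha transgene. All cells were kept under free fatty acid conditions, and the 9 libraries formed 3 groups of 3. The group called Veh received phosphate-buffered saline. EV_antaNC received extracellular vesicles of aged osteocytes that had been incubated for 30 min with a control antagomir, and EV_anta483 received vesicles incubated in the same way with an antagomir against miR-483-5p. Vesicles were given at 2 µg/ml per the labels. The labels name ultracentrifugation in one place and ultrafiltration in another for the step after that incubation, so the step is left open here. Total RNA was extracted. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

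For each library the authors deposited 1 table of counts per gene and 1 table of FPKM (fragments scaled by transcript length and by the total of the library). Reads were counted with HTSeq on the mouse build mm10, per the submitters' processing notes. The aligner, the annotation, the tool versions and the strand setting of the counting are not given in the sources used here. The tables listed 21959 genes, of which 16770 had a count in at least 1 library. The deposited FPKM of all 16770 genes equalled the count scaled by the column total and by 1 whole-number length per gene, within 0.001 base, so the FPKM held no further normalisation. Of the gene identifiers, 21851 matched the GENCODE M21 annotation of GRCm38 (the same assembly as mm10), 21723 of them protein-coding and 128 of other types, and 108 did not match. All files were used. Without a stated strand setting, reads of genes that overlap on opposite strands could not be told apart. Among 168 named genes, 47 overlapped an exon of a gene on the opposite strand, and for 4 of them the overlap reached 25% of the exon bases.

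Counts as deposited were the unit of the main test. Total counts per library ran from 17298814 to 21737643. Genes were kept by edgeR's filterByExpr (smallest count 10, smallest total count 15), which left 11562 genes holding at least 99.956% of the counts of each library. Libraries were scaled with TMM factors (trimmed mean of M values) and all 9 were fitted in one model with a coefficient per group and no covariate. Each of 3 comparisons was tested with edgeR's quasi-likelihood test, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with no limit on the fold change. Fold changes are given on the log2 scale with their standard errors (SE), and expression as CPM (counts scaled to one library total) with the SD over 3 libraries. Genes called in EV_antaNC against Veh and called with the opposite sign in EV_anta483 against EV_antaNC were counted as changed back. Because those comparisons share the EV_antaNC libraries, 40 simulations of unchanged groups gave the chance value of correlations and covariances. Such groups give almost no calls, so lists of the real lengths were taken by smallest p from each simulation. They gave the overlap that arises with no effect among independently drawn genes, a comparison added after the data were seen.

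The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists of genes numbered 27, of which 22 covered pathways and 5 covered markers of other cell types. The 24 lists with at least 3 tested members were tested with camera of limma (preset correlation of 0.01, adjusted over all lists and comparisons). The pathway lists covered PPAR-alpha and fatty acid oxidation, fatty acid synthesis, cholesterol synthesis and LDL uptake, fatty acid uptake with triglyceride and lipid droplet genes, lipoprotein secretion, endoplasmic reticulum chaperones, the integrated stress response, inflammation, the acute phase response, the interferon response, hepatocyte identity, glycolysis and hypoxia, mitochondrial DNA transcripts, nuclear respiratory chain genes, the NRF2 response, ferroptosis regulators, the cell cycle, the p53 response, TGF-beta and extracellular matrix, insulin and IGF signalling, autophagy and lysosome, and reported miR-483-5p targets. The marker lists were those of osteocytes, cholangiocytes, stellate cells, macrophages and endothelial cells. No list was chosen on these libraries. Named genes were, per comparison, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 2 CPM and groups that did not overlap, without predicted genes and pseudogenes. Further named genes were up to 4 called members of each list with the smallest adjusted p (or 2 as values where none was called), Igf2 and Alb, and the 10 genes changed back with the largest product of both fold changes. Called members outside this rule, named where a list held few calls, were chosen after their values were seen.

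Matches to the seed of miR-483-5p (its bases 2 to 8, or bases 2 to 7 followed by an A in the transcript) were searched in the longest annotated 3' UTR of each gene. Genes with a site were compared with genes without one, by the difference of the median log2 fold changes and by camera, and the difference was ranked among 60 words of the same base composition.

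Alternatives fixed beforehand were RLE size factors, library size alone, no filter on low counts, a filter at 1 CPM in 3 libraries, DESeq2, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes at 0.5 FPKM in 3 libraries, log2(FPKM + 1) without a filter, a fold of at least 2, the replicate number as a block, the 6 libraries compared alone, and leaving out each library in turn. For lists they were camera with an estimated correlation and fry. After the data were seen, an offset that removed each library's smooth trend on GC content and transcript length (loess span 0.5) was added, alone and with the block, as was a fit of the libraries numbered 2 and 3 only. The pipeline was tested on simulated data with 200 changed genes. At a fold of 1.5 it recovered 82% of 50 changed genes for EV_antaNC against Veh (11496 genes), 80% for EV_anta483 against EV_antaNC (11492 genes) and 82% for EV_anta483 against Veh (11492 genes). At a fold of 1.2 it recovered 40%, 28% and 38%, and at a fold of 2 it recovered 94%, 92% and 92%. False calls made up 3.09%, 3.85% and 6.63% of the calls. This simulation drew each gene independently, without a GC trend or a deviation shared by library number. Rates in the real libraries may therefore differ. Some genes called in these comparisons are not reported here by name, and the counts include them. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9.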

Results

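The data were gene counts from 9 libraries of AML12 mouse hepatocytes under free fatty acid load, with 3 libraries each for vehicle (Veh), for aged osteocyte vesicles pre-incubated with a control antagomir (EV_antaNC) and for the same kind of vesicles pre-incubated with an antagomir against miR-483-5p (EV_anta483). An antagomir is a modified oligonucleotide that binds and blocks a microRNA. The design asked what the vesicles changed in lipid-loaded hepatocytes, and what blocking miR-483-5p in them changed. No group received vesicles without an antagomir, and none received the control antagomir without vesicles. EV_antaNC against Veh therefore joins the effects of the vesicles and of the control antagomir. Total counts were 17825578, 21737643 and 17435514 for Veh 1 to 3, 18171471, 18535220 and 19439679 for EV_antaNC 1 to 3, and 17554451, 17298814 and 18628603 for EV_anta483 1 to 3. Libraries of a group differed by more than sampling noise, with a chi-square per gene between them of at least 2.18, where sampling alone gives 1.

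Markers of hepatocytes and of other cell types were read first. Hnf4a, a transcription factor of hepatocyte identity, lay between 49.0 and 66.1 CPM over the 9 libraries, and Tgfa, the mouse counterpart of the transgene behind this line, between 82.9 and 91.5 CPM. Krt19, a cytokeratin of bile duct cells, was abundant at 2323 to 2865 CPM, whereas Cyp2e1, a cytochrome of adult hepatocytes, had at most 1 count in any library. Sost and Dmp1, which mark osteocytes, had 0 counts in all 9 libraries, and Ptprc, a leukocyte marker, had at most 5. Igf2, whose intron holds the miR-483 gene (chromosome 7, 142650766 to 142666816, minus strand, GRCm38), also had 0 counts in each library. A count of 0 allows up to 0.139 to 0.176 CPM per library (3 counts), which covers counting error only. Exons of Igf2 share 62.8% of their bases with an overlapping gene on the same strand, so reads assigned to neither gene could also leave it at 0.

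The first principal component, with 22.6% of the variance, placed the EV_anta483 libraries at 12.3 to 13.9 and the other 6 libraries at -10.1 to -3.38. The second, with 17.6%, placed the libraries numbered 1 of all groups apart from those numbered 2 and 3. Mitochondrial transcripts took 3.98% ± 0.08 of the counts in Veh, 3.91% ± 0.12 in EV_antaNC and 3.88% ± 0.09 in EV_anta483 (SD, n = 3). The 50 most abundant genes took 17.01% ± 0.06 in Veh, 16.4% ± 0.14 in EV_antaNC and 17.3% ± 0.25 in EV_anta483 (SD, n = 3).

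Few genes were called between vesicles with the control antagomir and vehicle, and those called changed by small amounts. At a fold of 1.2 the simulated recovery in this comparison was 40%, so changes of that size can be missed. Luc7l3, a splicing factor with a serine and arginine rich domain (chromosome 11, 94287890 to 94321988, minus strand), rose from 215 ± 29 to 309 ± 48 CPM (SD, n = 3), a log2 fold change of 0.53 (SE 0.10). Srsf1, a regulator of splice site choice (chromosome 11, 88047373 to 88053755, plus strand), rose from 160 ± 12 to 222 ± 16 CPM (SD, n = 3), and Arglu1, a coactivator that also acts in splicing (chromosome 8, 8665075 to 8690521, minus strand), from 139 ± 1.7 to 183 ± 7.9 CPM (SD, n = 3). The largest rises were those of Ovgp1 at a log2 fold change of 0.81 (SE 0.20), Rex2 at 0.64, Aire at 0.61, Luc7l3 at 0.53, Clca1 at 0.52, Knl1 at 0.51, Prim1 at 0.50 and Spaca6 at 0.50. Aire drives the display of tissue antigens in the thymus, Knl1 is a kinetochore protein and Prim1 the catalytic subunit of primase. Falls were smaller: Fam13a at -0.27, Cops9 at -0.24, the ribosomal protein gene Rps2 at -0.24, Ddrgk1 at -0.23, the ferritin light chain gene Ftl1 at -0.23, Eif3g at -0.20, Thop1 at -0.19 and Suclg1 at -0.19. Ovgp1, Rex2, Rps2 and Ftl1 share sequence or exons with other genes and are uncertain.

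In this comparison 118 of 11562 genes were called, 94 higher and 24 lower in EV_antaNC. Of the called genes in edgeR 0 reached a fold of 2 and 4 a fold of 1.5, the median absolute log2 fold change was 0.26, and 1561 genes had an unadjusted p under 0.05. DESeq2 called 182 genes without a limit on the fold, and edgeR with the replicate number as a block called 522. The balance of higher and lower genes followed the scaling: 157 higher and 6 lower with library size alone, 49 and 2 on log2(FPKM + 1), and 40 and 53 with the trend on GC content and length removed. GC content moved with the group: of 5 equal groups of genes by GC content, the lowest (median 41.1%) held 62 of the 94 higher genes and the highest (57.7%) held 10 of the 24 lower ones. The trend also varied between libraries of a group. The Spearman correlation of a library's deviation from the mean with GC content was -0.0089, 0.095 and 0.23 in Veh 1 to 3. It was -0.27, -0.18 and -0.10 in EV_antaNC 1 to 3, and 0.082, 0.11 and 0.099 in EV_anta483 1 to 3. Of the 24 named calls of this comparison, those of Spaca6, Srsf1, Arglu1, Brd9 and Phka2 held without any single library, and 19 ended without at least 1. Knl1 was lost without Veh 3 and Luc7l3 without Veh 2 or 3 (adjusted p = 0.0701 at most for both). Ovgp1, Prim1, Cops9, Rps2 and Eif3g were lost without any of the 6 Veh and EV_antaNC libraries, at adjusted p up to 0.214, 0.169, 0.119, 0.170 and 0.162. Of these 6 libraries, Rex2 was lost without any but EV_antaNC 3 (0.123), Fam13a without any but EV_antaNC 1 (0.139), and Thop1 and Suclg1 without any but Veh 2 (0.250 and 0.248). Aire was lost without Veh 1, Veh 3 or EV_antaNC 2 (0.0718). Clca1 was lost without Veh 2, Veh 3 or EV_antaNC 3 (0.0880) and Ddrgk1 without Veh 2 or 3 or EV_antaNC 2 or 3 (0.128). Ftl1 was lost without Veh 2 or 3, any EV_antaNC library or EV_anta483 3 (0.242). With the GC trend removed Ovgp1 (0.0622), Rex2 (0.0597), Prim1 (0.0622), Rps2 (0.0592) and Thop1 (0.0549) were not called. Called genes numbered 71, 44 and 43 without Veh 1, 2 or 3, 73 and 53 without EV_antaNC 2 or 3, and 184 without EV_anta483 1.

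**Figure D1:**
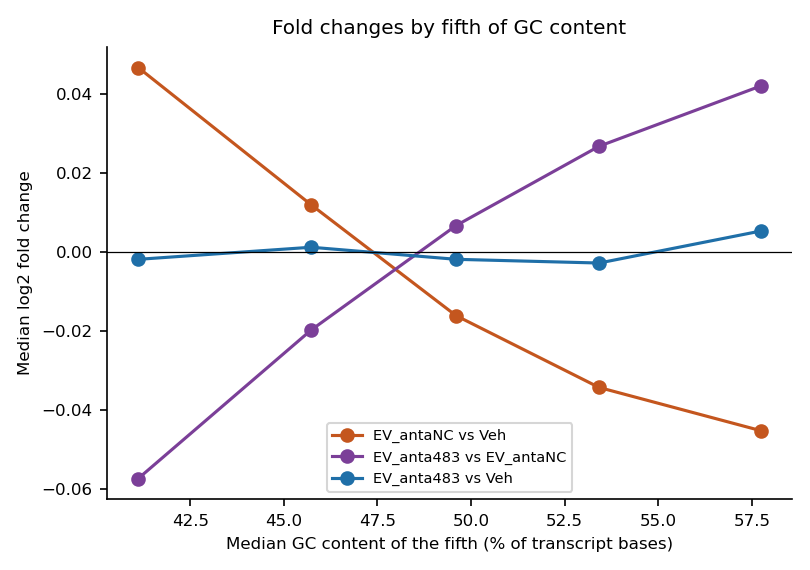
Median log2 fold change (y axis) of 5 equal groups of genes by GC content (x axis, median percent of transcript bases) for the 3 comparisons, with 1 point per group. From the lowest to the highest group the median went from 0.05 to -0.05 in EV_antaNC vs Veh and from -0.06 to 0.04 in EV_anta483 vs EV_antaNC, and stayed within 0.01 of 0 in EV_anta483 vs Veh.

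Cell cycle genes stood higher as a set in EV_antaNC than in Veh, while lists of lipid and energy metabolism stood slightly lower, by medians of under 0.1. None of these lists passed with an estimated correlation, which gave adjusted p = 0.612 for the cell cycle and cholesterol lists and 0.418 to 0.489 for the others. Of 32 tested cell cycle genes none was called over all genes and 7 were higher adjusted over the list alone, with a median log2 fold change of 0.20. Cenpe, a mitotic kinesin, gave 0.27 (adjusted p = 0.0697) and the mitotic kinase gene Cdk1 gave 0.21 (adjusted p = 0.0812). Camera gave the cell cycle list adjusted p = 0.000110, and adjusted p = 0.612 with an estimated correlation. The 40 nuclear respiratory chain genes had a median of -0.07, no call and 2 lower adjusted over the list alone (camera adjusted p = 0.000580; adjusted p = 0.418 with an estimated correlation). Atp5a1 gave -0.10 (adjusted p = 0.0793) and Cox4i1 -0.14 (adjusted p = 0.0843). Among 18 fatty acid synthesis genes there was no call and 2 were lower adjusted over the list alone, with a median of -0.07 (camera adjusted p = 0.00124; adjusted p = 0.418 with an estimated correlation). The desaturase genes Scd1 and Scd2 gave -0.10 (adjusted p = 0.0689) and -0.08 (adjusted p = 0.0983). Glycolysis and hypoxia genes included the calls of Pkm (pyruvate kinase) and Aldoa (aldolase), which fell by 0.12 on the log2 scale at adjusted p = 0.0132 and 0.0300, 2 of 30 tested; adjusted over the list alone 13 were lower and 1 higher. Their median was -0.06 but their mean 0.0012, and camera placed the list lower at adjusted p = 0.00285 (adjusted p = 0.418 with an estimated correlation). Pkm lost its call without Veh 2, Veh 3, EV_antaNC 2 or EV_antaNC 3 (adjusted p up to 0.129), and Aldoa without Veh 1, 2 or 3 or EV_antaNC 1 or 2 (up to 0.189) and with the GC trend removed (0.0648).

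Cholesterol synthesis and LDL uptake (24 tested, median -0.07, no call, 1 lower adjusted over the list alone) stood lower at camera adjusted p = 0.00350, and adjusted p = 0.612 with an estimated correlation. Srebf2, the transcription factor of that pathway, gave -0.11 (adjusted p = 0.0678). Autophagy and lysosome genes (32 tested, median -0.04, no call, 2 lower adjusted over the list alone) gave camera adjusted p = 0.00849, and adjusted p = 0.418 with an estimated correlation. The lysosomal protease gene Ctsd gave -0.14 (adjusted p = 0.0538), and is uncertain because 34.4% of its exon bases lie in another gene on the same strand. For 31 NRF2 genes, which answer oxidative stress, Ftl1 was the only call and 3 were lower adjusted over the list alone (median -0.05, camera adjusted p = 0.0165; adjusted p = 0.489 with an estimated correlation). TGF-beta and matrix genes (21 tested, median -0.08) had no call and 4 lower adjusted over the list alone, and PPAR-alpha and fatty acid oxidation genes (25 tested, median -0.06) had no call by either adjustment. Their camera adjusted p were 0.0202 and 0.0309, and adjusted p = 0.489 for both with an estimated correlation. Vim gave -0.09 (adjusted p = 0.0755) and Acadvl -0.11 (adjusted p = 0.253), the latter overlapping a gene on the other strand. Leaving out a library ended the list calls of PPAR-alpha (Veh 1, Veh 2, EV_antaNC 2 or 3; adjusted p up to 0.154), TGF-beta (Veh 3 or EV_antaNC 1; up to 0.288), NRF2 (Veh 2 or EV_antaNC 3; up to 0.0569), cholesterol (EV_antaNC 3; 0.0597) and autophagy (Veh 3; 0.0589). Removing the GC trend ended those of PPAR-alpha (0.0542) and TGF-beta (0.0521), and brought the 12 mitochondrial DNA transcripts past the threshold (0.000535). With fry, fatty acid synthesis, glycolysis, respiratory chain and autophagy passed and the other 5 did not.

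The remaining lists did not pass in EV_antaNC against Veh. Inflammation (18 tested, median 0.09, adjusted p = 0.234) and acute phase genes (12 tested, 0.05, adjusted p = 0.499) had no call. Lcn2, a neutrophil lipocalin in both lists, gave 0.29 (adjusted p = 0.134). Camera adjusted p was 0.0582 for the integrated stress response (23 tested, 2 lower adjusted over the list alone), where Ddit4 gave -0.16, and 0.0851 for mitochondrial DNA transcripts, where mt-Co2 gave -0.18 and 1 gene was lower adjusted over the list alone. It was 0.621 for fatty acid uptake and lipid droplets (25 tested; Mogat2 -0.28, adjusted p = 0.114), 0.879 for lipoprotein secretion (11 tested), 0.896 for endoplasmic reticulum chaperones (20 tested) and 0.918 for the interferon response (19 tested). It was 0.382 for ferroptosis regulators (17 tested, where Ftl1 was the only call, with 1 gene higher and 0 lower with library size alone, and 1 higher and 2 lower adjusted over the list alone), 0.741 for the p53 response (25 tested), 0.499 for insulin and IGF signalling (17 tested) and 0.499 for 7 tested reported targets of miR-483-5p (1 lower adjusted over the list alone), of which Timp2 gave -0.10 and Mapk3 -0.07. Hepatocyte identity genes (11 tested) gave 0.896, with Alb at 0.15 (SE 0.22). Cholangiocyte markers (6 tested, 2 lower adjusted over the list alone) gave 0.741, with Krt7 at -0.10 (adjusted p = 0.0573), and endothelial markers (4 tested) gave 0.808. No member of the other lists that did not pass was called by either adjustment. Osteocyte, stellate cell and macrophage lists had 2 tested members each and no list test. Spp1 and Runx2 gave 0.11 and 0.08, Des and Col1a1 -0.23 and -0.11, and Cd14 and Cd68 0.04 and -0.03, none called.

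With the miR-483-5p antagomir, genes of sterol and fatty acid synthesis stood higher and acute phase genes lower than with the control antagomir. As lists they did not pass with an estimated correlation (adjusted p = 0.418, 0.418 and 0.489). Cp, encoding the copper-carrying plasma protein ceruloplasmin (chromosome 3, 19957054 to 20009145, plus strand), lay at 334 ± 21 CPM in EV_antaNC and 172 ± 7.3 CPM in EV_anta483 (SD, n = 3), a log2 fold change of -0.96 (SE 0.04, adjusted p = 1.38e-11). Cd36, a receptor that takes up fatty acids (chromosome 5, 17781690 to 17888801, minus strand), fell from 13.8 ± 0.32 to 6.77 ± 0.69 CPM (SD, n = 3), a change of -1.02 (SE 0.11). Cyp51, the lanosterol demethylase of cholesterol synthesis (chromosome 5, 4081145 to 4104746, minus strand), rose from 373 ± 23 to 515 ± 36 CPM (SD, n = 3). Acss2, which makes acetyl-CoA from acetate (chromosome 2, 155517948 to 155585724, plus strand), rose from 53.5 ± 3.8 to 83.1 ± 6.6 CPM (SD, n = 3). The largest rises were those of Fibcd1 at 1.87 (SE 0.25; 0.944 to 3.48 CPM), Shc2 at 1.35, Prl2c3 at 1.3, the acetyl-CoA carboxylase gene Acacb at 0.84, the collagen gene Col6a3 at 0.83, Unc13d at 0.79, Irgc1 at 0.76 and Ggt7 at 0.74. The largest falls were those of Cd36, Il17re at -1.01, Palmd at -1.0, Akr1c14 at -0.98, Cp, Snap25 at -0.95, Fam171b at -0.93 and Nup210l at -0.86. Prl2c3 belongs to a family of near-identical genes and is uncertain. Irgc1 lost its call without EV_antaNC 1 or 2 or EV_anta483 2 (adjusted p up to 0.106), and Ggt7 without EV_antaNC 2 or EV_anta483 1 (up to 0.0809).

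**Figure D2:**
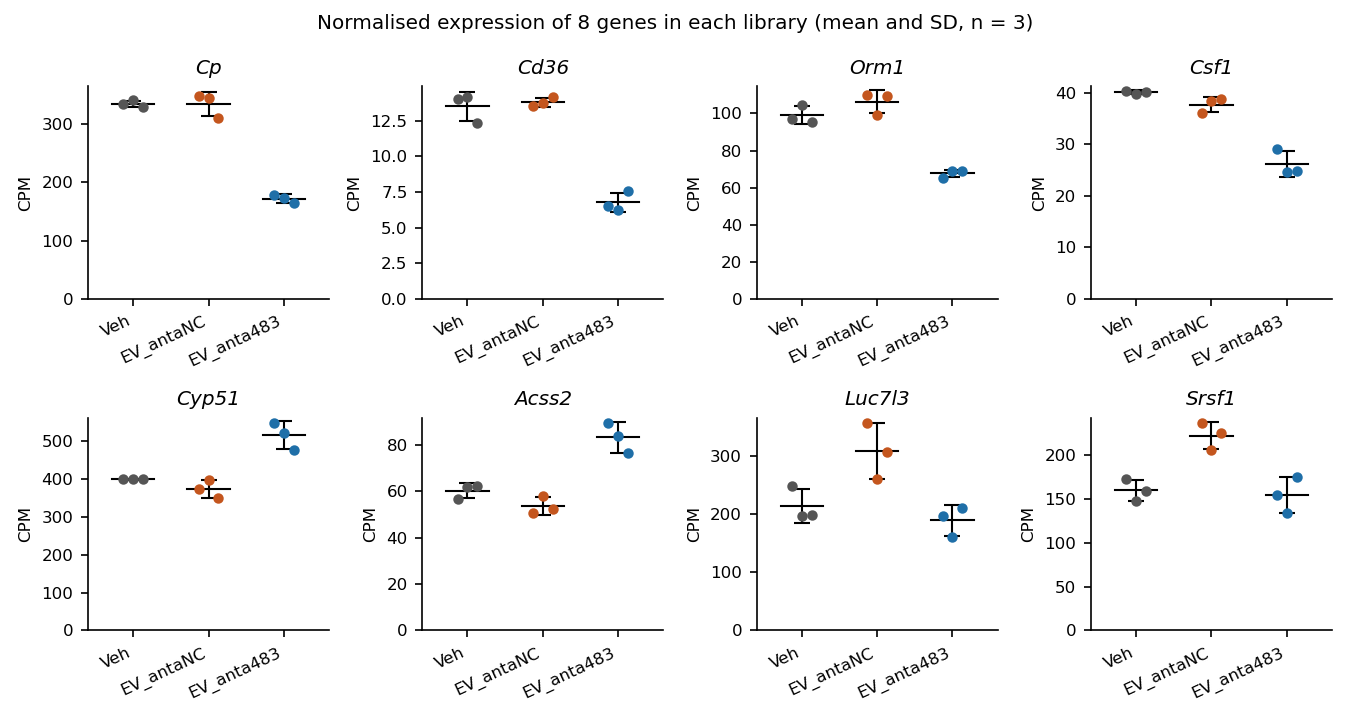
Normalised expression (CPM, y axis from 0) of 8 genes in the 3 groups (x axis); points are libraries, horizontal lines the group means and bars the SD (n = 3). Cp, Cd36, Orm1 and Csf1 were lower in EV_anta483 than in both other groups and Cyp51 and Acss2 higher, whereas Luc7l3 and Srsf1 were highest in EV_antaNC.

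Between these groups 1698 of 11562 genes were called, 878 higher and 820 lower in EV_anta483. Of these, 30 reached a fold of 2 and 103 a fold of 1.5, and the median absolute log2 fold change was 0.21. The split was 530 higher and 1155 lower with library size alone, 405 and 926 on log2(FPKM + 1), and 1215 and 595 with the trend on GC content and length removed. Of 5 equal groups of genes by GC content, the lowest held 90 higher and 351 lower genes and the highest 217 and 49. Leaving out EV_anta483 2 lowered the count to 1005.

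Of 24 tested genes of cholesterol synthesis and LDL uptake, 19 rose and none fell (19 adjusted over the list alone), with a median of 0.25. Camera gave adjusted p = 1.67e-12, and adjusted p = 0.418 with an estimated correlation. Besides Cyp51 at 0.47 (SE 0.04), Mvd rose by 0.45 (SE 0.05), the lanosterol synthase gene Lss by 0.38 (SE 0.03) and Nsdhl by 0.33 (SE 0.04). Of 18 fatty acid synthesis genes 10 rose and 1 fell, and adjusted over the list alone 10 rose and 3 fell, with a median of 0.18 (camera adjusted p = 0.00131; adjusted p = 0.418 with an estimated correlation). Acss2 rose by 0.63 (SE 0.06), Scd1 by 0.28, the desaturase gene Fads2 by 0.23 and Scd2 by 0.21. Gpam, which starts glycerolipid synthesis, fell by 0.21 and was named after its value was seen. Scd1 and Scd2 are close copies. Fatty acid uptake and lipid droplet genes went both ways, with 5 higher and 1 lower of 25 tested, 8 and 4 adjusted over the list alone, and camera adjusted p = 0.507. Fabp4, a fatty acid carrier (chromosome 3, 10204088 to 10208576, minus strand), rose by 0.50 (SE 0.05), Lpin1 by 0.36 and Mogat2 by 0.36, while Cd36 fell. Fabp5 and Acsl1, named after their values were seen, rose by 0.20, and Acsl1 was lost without EV_antaNC 2 or EV_anta483 1 (adjusted p up to 0.102). Of 11 lipoprotein genes Lipc (hepatic lipase) rose from 0.529 to 1.42 CPM and Apoa1 fell by 0.68 (adjusted p = 0.0238), with 1 higher and 3 lower adjusted over the list alone and camera adjusted p = 0.996. Apoa1 lost its call without EV_antaNC 3 or EV_anta483 1 or 3 (adjusted p up to 0.156). In the fatty acid oxidation list (25 tested, none adjusted over the list alone, adjusted p = 0.741) the only call over all genes was Vnn1 at -0.62 (adjusted p = 0.0491), which was lost with the GC trend removed (0.0682) and without Veh 2 or 3, EV_antaNC 1 or 2, or any EV_anta483 library (up to 0.267). With the GC trend removed 1 gene of this list was higher and 0 lower, and the median turned from -0.03 to 0.00053, whereas with library size alone 0 were higher and 3 lower.

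Genes of the integrated stress response, which answers amino acid shortage and unfolded proteins, rose in 11 of 23 tested and fell in none (16 and 0 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 1.36e-06; adjusted p = 0.489 with an estimated correlation). The transcription factor gene Atf3 rose by 0.56 (SE 0.09), the pseudokinase gene Trib3 by 0.42, the amino acid transporter gene Slc7a5 by 0.28 and Aldh18a1, of proline synthesis, by 0.27. Glycolysis and hypoxia genes rose in 17 of 30 and fell in none, and adjusted over the list alone 20 rose and 1 fell, with a median of 0.12 (camera adjusted p = 7.56e-06; adjusted p = 0.418 with an estimated correlation). Aldoa rose by 0.22, Pkm by 0.17, Gpi1 by 0.16 and Tpi1 by 0.14. Of 31 NRF2 genes 10 rose and 1 fell, and adjusted over the list alone 11 rose and 3 fell, with a median of 0.08 (camera adjusted p = 0.00468; adjusted p = 0.487 with an estimated correlation). The glutathione transferase gene Gsta1 rose by 0.42, Ftl1 by 0.30, the efflux pump gene Abcc1 by 0.26 and Tkt by 0.20, while Gstm1, named after its value was seen, fell by 0.14 (adjusted p = 0.0493). Gstm1 was lost without any library but EV_antaNC 3 and EV_anta483 2 (up to 0.202) and with the GC trend removed (0.0579). Ftl1 and Gsta1 have near-identical copies, and Ftl1 overlaps a gene on the other strand. With fry the stress response list did not pass (adjusted p = 0.0510), while those of fatty acid uptake and lipid droplets (0.0421) and of autophagy and lysosome (0.0253), which did not pass camera, did.

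Acute phase genes, which the liver secretes in inflammation, fell in 5 of 12 tested and rose in none (5 and 0 adjusted over the list alone), with a median of -0.35. Camera gave adjusted p = 0.00453, and adjusted p = 0.489 with an estimated correlation. Orm1, encoding orosomucoid (chromosome 4, 63344560 to 63348163, plus strand), fell from 106 ± 6.1 to 67.7 ± 2.0 CPM (SD, n = 3), a change of -0.65 (SE 0.05, adjusted p = 6.80e-08). Lbp, which binds bacterial lipopolysaccharide (chromosome 2, 158306493 to 158332852, plus strand), fell by 0.31 (SE 0.04), Lcn2 by 0.39 (SE 0.09) and Orm2 by 0.69 (SE 0.18, adjusted p = 0.0116). The call of Orm2, a close copy of Orm1, was lost without EV_antaNC 3 (adjusted p = 0.0532). Hpx, which binds haem, fell by 0.83 and was named after its value was seen. Its call was lost without EV_antaNC 1 or 2 or any EV_anta483 library (up to 0.166). The inflammation list did not pass (18 tested, 1 higher and 5 lower, 1 and 6 adjusted over the list alone, median -0.12, adjusted p = 0.0934). This list did pass with the replicate number as a block. In it the macrophage growth factor gene Csf1 (chromosome 3, 107741048 to 107760469, minus strand) fell by 0.53 (SE 0.06) and the monocyte chemokine gene Ccl2 by 0.73 (SE 0.13), while Nfkb2 rose by 0.27. Nfkbiz and Cxcl5, named after their values were seen, fell by 0.42 and 0.57. Nfkbiz was lost without EV_antaNC 2 (0.0723), and Cxcl5 without EV_antaNC 2 or 3 or EV_anta483 1 or 3 (up to 0.0802) and with the GC trend removed (0.0519). Interferon response genes (19 tested, 1 higher and 2 lower by both adjustments, over all genes and adjusted over the list alone, adjusted p = 0.808) held Ifit2 at -0.46, Oasl1 at 0.39 and Bst2 at -0.19. Oasl1 lost its call without EV_antaNC 1 or 3 or EV_anta483 1 or 2 (adjusted p up to 0.120), and Bst2 without EV_antaNC 1 or 3 or EV_anta483 2 or 3 (up to 0.144).

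Hepatocyte identity genes did not pass as a list (11 tested, 2 lower, and 2 adjusted over the list alone, adjusted p = 0.741). Ttr, encoding transthyretin, fell by 1.28 (SE 0.31, 1.71 to 0.696 CPM), and Alb by 0.76 (SE 0.24, adjusted p = 0.0387), from 5.79 ± 1.3 to 3.42 ± 1.6 CPM (SD, n = 3). Both are low in these cells, and the call of Alb was lost without EV_antaNC 2 or EV_anta483 1 or 3 (adjusted p up to 0.182), that of Ttr without EV_antaNC 1 (0.0589). Krt19, a bile duct marker, rose by 0.19 (adjusted p = 0.000344), and Spp1, shared by the cholangiocyte and osteocyte lists, fell by 0.19 (adjusted p = 0.0194), a call lost without EV_antaNC 2 or EV_anta483 2 or 3 (up to 0.143) and with the GC trend removed (0.160). The 6 cholangiocyte markers (1 higher and 1 lower adjusted over the list alone) gave adjusted p = 0.692 and 4 endothelial markers 0.655. Stellate cell and macrophage genes were not called, with Col1a1 at -0.51 and Cd68 at 0.34.

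The other lists did not pass in EV_anta483 against EV_antaNC. Autophagy and lysosome genes (32 tested, 6 higher and 1 lower, 8 and 1 adjusted over the list alone) gave adjusted p = 0.0550, and 0.0333 with the GC trend removed. The receptor gene Sqstm1 rose by 0.22, Ctsd by 0.17 and Npc1 by 0.17, while the acid lipase gene Lipa fell by 0.20. Ctsd shares exons with a gene on the same strand and is uncertain. The p53 response (25 tested, 7 higher and none lower, 8 and 1 adjusted over the list alone) gave 0.108, with the cell cycle inhibitor gene Cdkn1a at 0.22, Gadd45b at 0.27 and Gadd45a at 0.26. Ferroptosis regulators (17 tested, 5 higher and 1 lower, 6 and 1 adjusted over the list alone) gave 0.174. The transferrin receptor gene Tfrc fell by 0.40, while Ftl1 rose by 0.30, Ncoa4 by 0.24, Hmox1 by 0.22 and, named after their values were seen, Chac1 by 0.37 and Fth1 by 0.13. TGF-beta and matrix genes (21 tested, 4 higher and 2 lower, as many adjusted over the list alone) gave 0.418, with Vim at 0.25, Fn1 at 0.27 and Tgfbr1 at -0.28, beside Tgfb1 at 0.18 and Thbs1 at -0.37, named after their values were seen. Endoplasmic reticulum chaperones (20 tested, 2 higher and 3 lower, 2 and 5 adjusted over the list alone) gave 0.662, with Xbp1 and Herpud1 at 0.23, Dnajb11 at -0.29, Hsp90b1 at -0.13 and Pdia3, named after its value was seen, at -0.12. With the GC trend removed 4 chaperone genes were higher and 1 lower. Insulin and IGF signalling (17 tested, 2 higher and 1 lower, 2 and 2 adjusted over the list alone) gave 0.808, with Tsc22d3 at 0.26, Foxo3 at 0.16 and Igfbp4 at -0.18, and 7 reported miR-483-5p targets (1 higher and 2 lower adjusted over the list alone) gave 0.982, with Mapk3 at 0.19 and Alcam at -0.16. Mitochondrial DNA transcripts (12 tested, 1 higher and 3 lower, 3 and 3 adjusted over the list alone) gave 0.808, with mt-Cytb and mt-Nd1 at -0.15, mt-Atp6 at -0.20 and mt-Nd6 at 0.23. With the GC trend removed this list turned to 4 higher and 0 lower, with its median going from -0.05 to 0.07. The 40 nuclear respiratory chain genes gave 0.856, with Cox7b at -0.20, and 32 cell cycle genes 0.883, with Rrm1 at -0.18, each the only call by both adjustments. Single libraries ended the calls of Npc1 (EV_antaNC 1; adjusted p = 0.0665), Gadd45a and Rrm1 (EV_antaNC 1 or EV_anta483 2; up to 0.0670 and 0.101), Hsp90b1 (EV_antaNC 1 or EV_anta483 3; 0.0978), Foxo3 (EV_antaNC 1 or 2 or EV_anta483 2 or 3; 0.0890), and Alcam (EV_antaNC 2 or 3 or EV_anta483 2 or 3; 0.0817). So did those of mt-Cytb (EV_antaNC 1 or 2 or EV_anta483 2 or 3; 0.152), mt-Atp6 (EV_antaNC 3 or EV_anta483 2 or 3; 0.192), mt-Nd6 (EV_antaNC 1 or 2 or any EV_anta483 library; 0.167) and mt-Nd1 (EV_antaNC 2 or EV_anta483 1 or 3; 0.285). Tgfb1 was lost without any of the 9 libraries (up to 0.188), Chac1 without any but Veh 1, EV_antaNC 2 and EV_anta483 1 (0.222), Fth1 without EV_antaNC 2 or EV_anta483 2 (0.0646), and Pdia3 without EV_antaNC 1 or 2 or EV_anta483 2 or 3 (0.148) and with the GC trend removed (0.112). With that trend removed the cell cycle list held 1 higher gene and 0 lower. The calls of Hsp90b1, Rrm1, Alcam, mt-Cytb, mt-Nd1 and mt-Atp6 also ended with the GC trend removed (adjusted p = 0.241, 0.0531, 0.0781, 0.357, 0.618 and 0.479).

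Cells given vesicles with the miR-483-5p antagomir had lower Cp and Cd36 than vehicle cells. Lists of sterol synthesis and the cell cycle stood higher, with 12 of 24 and 5 of 32 genes called, and the acute phase list lower, with 3 of 12 called, and none passed with an estimated correlation (adjusted p = 0.418, 0.692 and 0.492). Cp lay at 334 ± 5.9 CPM in Veh and 172 ± 7.3 CPM in EV_anta483 (SD, n = 3), a log2 fold change of -0.96 (SE 0.04, adjusted p = 1.37e-11), and Cd36 at 13.5 ± 1.0 and 6.77 ± 0.69 CPM (SD, n = 3), a change of -0.99. Havcr2, encoding the immune receptor TIM-3 (chromosome 11, 46454935 to 46481255, plus strand), rose from 18.1 ± 0.7 to 31.1 ± 1.8 CPM (SD, n = 3). The largest rises were those of Fibcd1 at 1.69 (SE 0.24), Prl2c3 at 1.49, Serpinb5 at 1.07, Shc2 at 1.02, Krt78 at 0.93, Amz1 at 0.87, Cenpu at 0.82 and Havcr2 at 0.78. After Cd36 and Cp, the largest falls were those of Akr1c14 at -0.94, Apon at -0.93, the fibroblast growth factor receptor gene Fgfr2 at -0.93, Kifc3 at -0.90, Fam171b at -0.87 and Palmd at -0.85. Cenpu and Kifc3 overlap genes on the other strand. Calls were lost without 1 library for Serpinb5 (Veh 2 or EV_anta483 3; adjusted p up to 0.0854), Shc2 (Veh 2 or EV_anta483 2 or 3; 0.0839), Krt78 (Veh 2 or EV_anta483 2; 0.0824) and Amz1 (any Veh library or EV_anta483 2 or 3; 0.0907). So were those of Cenpu (Veh 2 or 3, EV_antaNC 2 or 3 or EV_anta483 1 or 2; 0.187), Kifc3 (Veh 2 or EV_anta483 3; 0.103) and Fam171b (EV_anta483 2; 0.0623).

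In this comparison 754 of 11562 genes were called, 354 higher and 400 lower, with 17 at a fold of 2 and 44 at a fold of 1.5. The median absolute log2 fold change was 0.22. On log2(FPKM + 1) the split was 184 higher and 354 lower. Called genes were spread over GC content, with 77 higher and 86 lower in the lowest of the 5 GC groups and 59 and 64 in the highest. The count was 322 without Veh 2, 422 without Veh 3, 361 without EV_anta483 2 and 459 without EV_anta483 3.

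Cholesterol synthesis and LDL uptake rose in 12 of 24 genes and fell in none (18 and 0 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 1.12e-10; adjusted p = 0.418 with an estimated correlation). Cyp51 and Mvd rose by 0.37, and Lss and the sterol sensor gene Insig1 by 0.31. Integrated stress response genes rose in 9 of 23 and fell in 1 (12 and 1 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 6.12e-05; adjusted p = 0.571 with an estimated correlation). Trib3 rose by 0.42, Atf3 by 0.41, the cystine transporter gene Slc7a11 by 0.30 and Aldh18a1 by 0.21. Psat1, of serine synthesis, fell by 0.13, was named after its value was seen, and was lost without Veh 2 or 3 or EV_anta483 1 or 3 (adjusted p up to 0.136). Slc7a11 lost its call without EV_anta483 2 and Aldh18a1 without Veh 2 or EV_anta483 2 (adjusted p up to 0.0618 and 0.0678). Of 32 cell cycle genes 5 rose and none fell, and adjusted over the list alone 11 rose and 1 fell, with a median of 0.20 (camera adjusted p = 0.00124; adjusted p = 0.692 with an estimated correlation). The mitotic kinesin genes Kif20a and Cenpe rose by 0.42 and 0.33, the cyclin gene Ccna2 by 0.32 and the topoisomerase gene Top2a by 0.28, beside Cenpf at 0.33, named after its value was seen and lost without Veh 2 or 3, EV_antaNC 3 or any EV_anta483 library (up to 0.219). Kif20a overlaps a gene on the other strand. Cenpe lost its call without Veh 3, Ccna2 without Veh 2 or 3, and Top2a without Veh 2 or 3 or any EV_anta483 library (adjusted p up to 0.0513, 0.0744 and 0.159). With fry, cholesterol and glycolysis passed and the other 5 lists did not.

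Acute phase genes fell in 3 of 12 and rose in none, and adjusted over the list alone 5 fell and 1 rose, with a median of -0.30 (camera adjusted p = 0.00764; adjusted p = 0.492 with an estimated correlation). Orm1 fell by 0.55 (SE 0.05), Lbp by 0.38 (SE 0.04) and Orm2 by 0.64 (adjusted p = 0.0329), the last lost without any of the 6 libraries compared (adjusted p up to 0.125). Glycolysis and hypoxia genes rose in 5 of 30 (7 adjusted over the list alone), with a median of 0.06 (camera adjusted p = 0.00281; adjusted p = 0.418 with an estimated correlation). They were Bhlhe40 and P4ha1 at 0.17, Gapdh at 0.15, Kdm3a at 0.14 and Aldoa, named after its value was seen, at 0.10. Bhlhe40 was lost without Veh 2, Gapdh without Veh 2 or EV_anta483 2, P4ha1 without Veh 2 or EV_anta483 2 or 3, and Kdm3a without any Veh library or EV_anta483 2 or 3, at adjusted p up to 0.0586, 0.102, 0.114 and 0.145. Aldoa was lost without any Veh library, EV_antaNC 2 or EV_anta483 2 (up to 0.180). Nuclear respiratory chain genes fell in 2 of 40 (none adjusted over the list alone), with a median of -0.04 (camera adjusted p = 0.00573; adjusted p = 0.487 with an estimated correlation). These were Cox7a2 at -0.17 and Cox4i1 at -0.13, and both were lost without any Veh library, EV_antaNC 2, or EV_anta483 2 or 3, and Cox4i1 also without EV_antaNC 3 (up to 0.185 and 0.188). PPAR-alpha and fatty acid oxidation genes fell in 1 of 25, the acyl-CoA thioesterase gene Acot1 at -0.22 (1 adjusted over the list alone), with a median of -0.06 (camera adjusted p = 0.0172; adjusted p = 0.487 with an estimated correlation). Acot1 was lost without Veh 2 or 3 or EV_anta483 3 (up to 0.118). Without EV_anta483 1 the acute phase list gave adjusted p = 0.0927 and the PPAR-alpha list 0.0988.

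Among lists that did not pass, fatty acid synthesis (18 tested, 5 higher and 2 lower, 9 and 2 adjusted over the list alone) gave adjusted p = 0.0550. Acss2 rose by 0.46, Scd1 by 0.17 and Scd2 by 0.13, while Gpam fell by 0.22. Fads2 at 0.16, Slc25a1 at 0.17 and Acaca at -0.16, named after their values were seen, were also called. Slc25a1 was lost without Veh 1 or 2 or EV_anta483 1 or 2 (adjusted p up to 0.128), and Acaca without Veh 1 or 3 or EV_anta483 2 or 3 (0.130). Lipid droplet genes (25 tested, 3 higher and 3 lower, 4 and 4 adjusted over the list alone) gave 0.741. Fabp4 rose by 0.55 and Fabp5 by 0.21, Cd36 and the triglyceride lipase gene Pnpla2 fell by 0.99 and 0.24, and Lpin1 at 0.23 and Plin2 at -0.18, named after their values were seen, were the other calls. Lpin1 was lost without Veh 1 or EV_anta483 2 or 3 (up to 0.0705), and Plin2 without Veh 2 or EV_anta483 3 (0.0641). Mitochondrial DNA transcripts (12 tested, 0 higher and 3 lower, 4 lower adjusted over the list alone, median -0.13) gave 0.0550, with mt-Co3 at -0.23, mt-Co2 at -0.18 and mt-Cytb at -0.17. This list did pass with the replicate number as a block. The call of mt-Co3 was lost without Veh 2 or 3 or EV_anta483 3 (adjusted p up to 0.190), that of mt-Co2 without Veh 1 or 3 or EV_anta483 2 or 3 (0.195) and that of mt-Cytb without Veh 2 or 3 or EV_anta483 2 or 3 (0.167). Those of mt-Co2 and mt-Co3 were also lost with the GC trend removed (0.0640 and 0.0697). The p53 response (25 tested, 3 higher, 7 adjusted over the list alone) gave 0.121, with Gadd45a at 0.29 and Igfbp3 at 0.29. NRF2 genes (31 tested, 4 higher and 1 lower, 9 and 2 adjusted over the list alone) gave 0.174, with Gsta1 at 0.37, Abcc1 at 0.16, Slc7a11 at 0.30 and Gstm1 at -0.23, beside Tkt at 0.10, named after its value was seen and lost without any Veh library or EV_anta483 2 (up to 0.132). Without EV_anta483 2 the calls of Gadd45a (adjusted p = 0.0623) and Slc7a11 (0.0618) ended, and that of Igfbp3 ended without any Veh library or EV_anta483 1 or 2 (up to 0.152).

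The inflammation list gave adjusted p = 0.499 (18 tested, 1 higher and 2 lower by both adjustments, over all genes and adjusted over the list alone), with Csf1 at -0.61 (SE 0.06), Ccl2 at -0.50 and Nfkb2 at 0.20. TGF-beta genes gave 0.807 (21 tested, 3 higher and 3 lower, as many adjusted over the list alone), with Vim at 0.16, Fn1 at 0.18, Thbs1 at -0.36, Timp2 at -0.18 and Tgfbr1, named after its value was seen, at -0.20, lost without Veh 2 or EV_anta483 2 (up to 0.0801). Ccl2 was lost without Veh 2 or 3 or EV_anta483 1 or 3 (adjusted p up to 0.146), and Nfkb2 without Veh 1 or 2 or EV_anta483 2 (0.0746). Endoplasmic reticulum chaperones gave 0.497 (20 tested, 2 higher and 1 lower adjusted over the list alone), with Xbp1 at 0.21, lost without EV_anta483 2 (0.0527), and Dnajb11 at -0.25, lost without Veh 2 or 3 or EV_anta483 2 (up to 0.0835). Ferroptosis regulators gave 0.741 (17 tested, 2 higher and 1 lower, 4 and 2 adjusted over the list alone), with Slc7a11 at 0.30, lost without EV_anta483 2 (0.0618), Tfrc at -0.22, lost without Veh 2 or EV_anta483 2 (up to 0.0773), and Ncoa4 at 0.21, lost without Veh 2 (0.0614). Autophagy gave 0.808 (32 tested, 1 higher and 1 lower adjusted over the list alone), with Lipa at -0.25 and Sqstm1 at 0.18. Insulin and IGF signalling gave 0.879 (17 tested, 2 higher and 3 lower adjusted over the list alone), with Igfbp4 at -0.25 and Tsc22d3 at 0.22, the latter lost without Veh 2 or 3 or EV_anta483 2 (up to 0.161). With the GC trend removed or library size alone this list had 1 gene called higher and 2 lower, against 2 and 1. Lipoprotein genes gave 0.996 (11 tested, 1 higher and 2 lower adjusted over the list alone), with Lipc at 1.23, lost without Veh 1 or 2 or EV_anta483 2 (up to 0.0666). The interferon response gave 0.741 (19 tested, 1 higher and 2 lower adjusted over the list alone), with Ifit2 at -0.46. Reported miR-483-5p targets gave 0.741 (7 tested, 2 higher and 2 lower adjusted over the list alone), with Timp2 called. Hepatocyte identity gave 0.611 (11 tested, 1 lower adjusted over the list alone), with Ttr at -1.21, lost without any Veh library or EV_anta483 2 or 3 (up to 0.0951), and Alb, not called, at -0.60 (adjusted p = 0.154). Cholangiocyte markers (6 tested) gave 0.864, with Krt19 at 0.09, and endothelial markers (4 tested) 0.741. None of Runx2 at 0.08, Spp1 at -0.08, Col1a1 at -0.62, Des at -0.05, Cd68 at 0.32 and Cd14 at 0.08 was called. Over the 72 list tests the median, the mean and the test differed in sign in 16, of which the glycolysis list in EV_antaNC against Veh was the only one past the threshold.

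**Figure D3:**
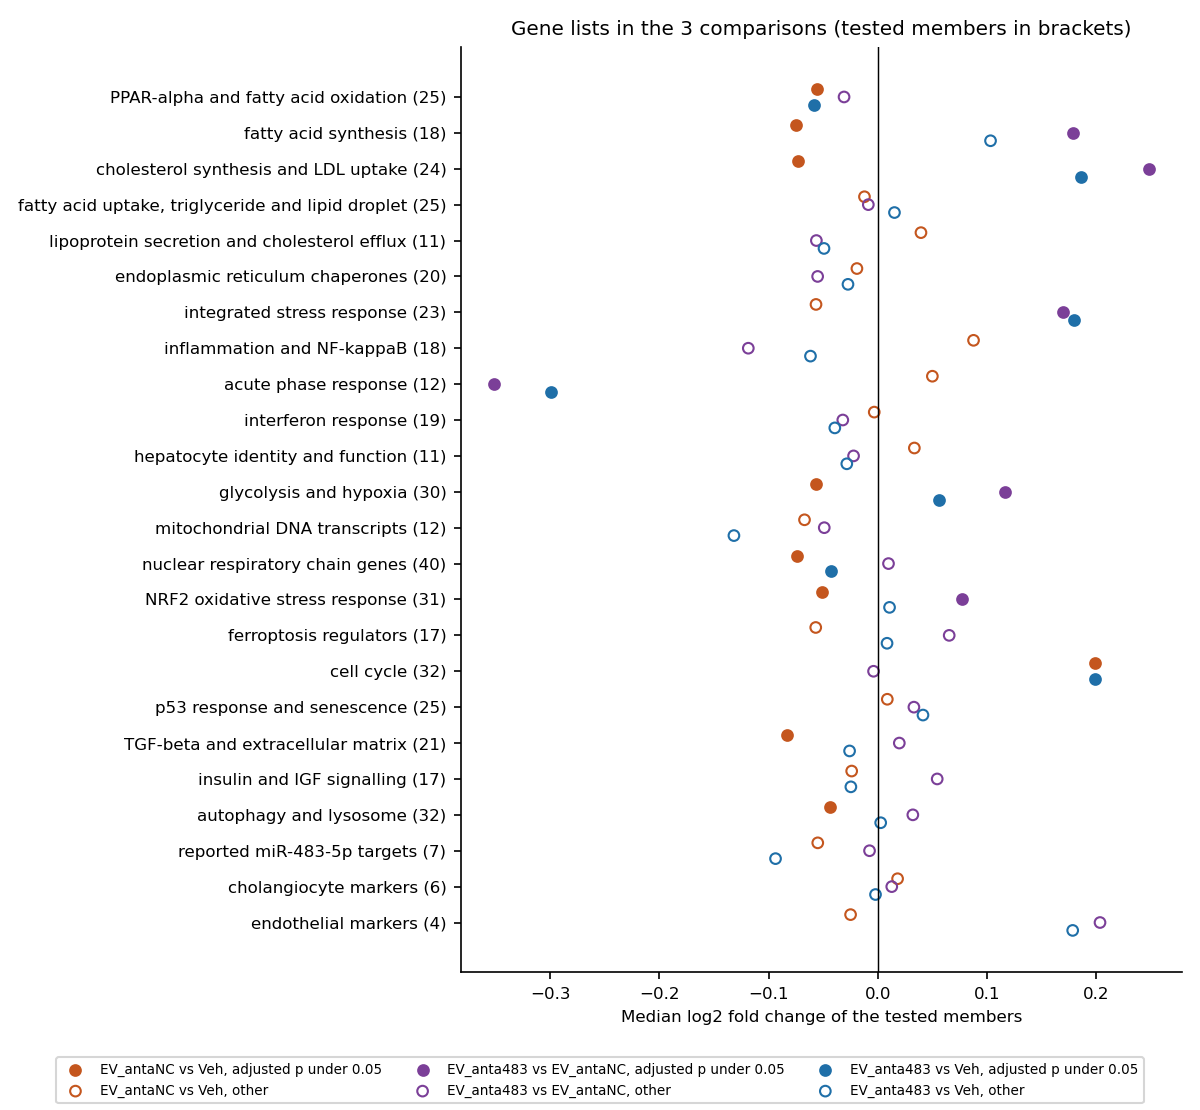
Median log2 fold change (x axis) of the tested members of each of 24 lists (y axis, number tested in brackets) in the 3 comparisons; filled points passed camera at an adjusted p under 0.05 and open points did not. Cholesterol synthesis stood at 0.25 and 0.19 in EV_anta483 against EV_antaNC and Veh and at -0.07 in EV_antaNC against Veh, and the acute phase response at -0.35, -0.30 and 0.05.

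Luc7l3, Srsf1 and Arglu1 were among the genes called in EV_antaNC against Veh and called with the opposite sign in EV_anta483 against EV_antaNC. There were 99 such genes, 79 higher and 20 lower in EV_antaNC than in Veh and in EV_anta483, and 91 of the 99 were not called between EV_anta483 and Veh. The 10 with the largest changes were Ovgp1 (0.81 against Veh and -0.73 in EV_anta483 against EV_antaNC), Luc7l3 (0.53 and -0.70), Clca1 (0.52 and -0.68), Gm14443 (0.68 and -0.46), the sperm membrane gene Spaca6 (0.50 and -0.55), Srsf1 (0.48 and -0.52), Arglu1 (0.40 and -0.61), the chromatin remodelling gene Brd9 (0.42 and -0.52), Gabre (0.41 and -0.52) and the phosphorylase kinase subunit gene Phka2 (0.41 and -0.51). Luc7l3 stood at 190 ± 26 CPM, Srsf1 at 154 ± 21 CPM and Arglu1 at 120 ± 8.6 CPM in EV_anta483 (SD, n = 3), and Arglu1 was also below Veh by -0.21 (adjusted p = 0.0131), a call lost without Veh 3 or EV_anta483 2 (up to 0.0854). Only 1 gene was called with the same sign in both comparisons. Independent lists of these sizes would share 6.67 genes higher and 1.82 lower in EV_antaNC, and 40 simulations of unchanged groups called almost no gene (0.025 on average in EV_antaNC against Veh) and shared 0. Lists of the real lengths, 118 and 1698 genes, taken by smallest p from each simulation shared 59.2 genes of opposite sign on average (44 to 73), with no effect in any group. Here and for the overlaps below, the simulations drew each gene independently, without a GC trend or a deviation shared by library number. Overlap from such structure, with no treatment effect, is therefore not in the simulated values. Both comparisons hold the EV_antaNC libraries, so their fold changes are negatively related by construction: r was -0.47 over genes against -0.49 in the simulations, and the covariance -0.0174 against -0.00953, a difference of -0.00790. The 3 shared libraries cannot be split into parts of at least 2, so part of the excess may come from them. Against Veh, the call of Gm14443 was lost without any Veh library or EV_antaNC 1 or 3 (adjusted p up to 0.128), that of Gabre without Veh 1 or EV_antaNC 2 (0.0603) and that of Ovgp1 without any of the 6 libraries (0.214). Luc7l3 was lost there without Veh 2 or 3 (0.0701) and Clca1 without Veh 2, Veh 3 or EV_antaNC 3 (0.0880). In EV_anta483 against EV_antaNC, Gm14443 was lost without EV_antaNC 1 or EV_anta483 1 or 2 (0.216) and Ovgp1 without EV_antaNC 3 or EV_anta483 2 (0.0842). With the GC trend removed 51 of the 99 stayed changed back, and the calls of Gm14443 (0.0533 and 0.0829) and of Ovgp1 against Veh (0.0622) ended. The number changed back was 61, 39 and 41 without Veh 1, 2 or 3, and 62 and 49 without EV_antaNC 2 or 3. With the replicate number as a block it was 359.

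**Figure D4:**
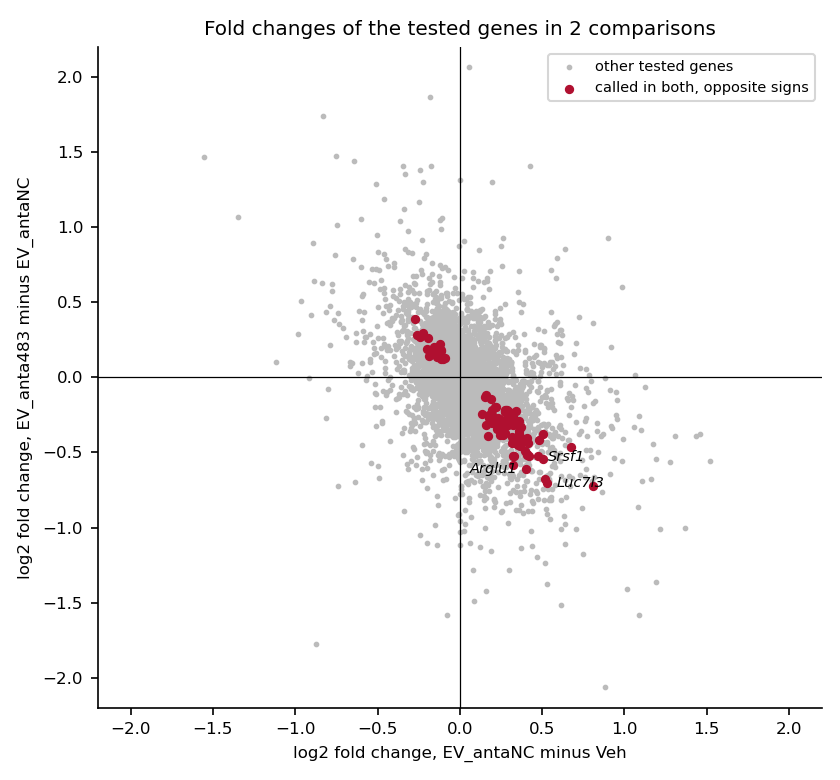
Log2 fold changes of the 11562 tested genes in EV_antaNC minus Veh (x axis) and in EV_anta483 minus EV_antaNC (y axis); the 99 genes called in both with opposite signs are red. Since both axes use the EV_antaNC libraries, unchanged genes also lie along a falling diagonal (r -0.47 observed, -0.49 in simulated unchanged groups).

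The 99 genes were drawn from the 118 called in EV_antaNC against Veh, so at most 118 of the 1698 genes called in EV_anta483 against EV_antaNC could be changed back. Of the 1698 genes, 531 (31.3%), among them Cp, Cd36, Orm1, Csf1 and Cyp51, were also called with the same sign against Veh without being changed back. The other 1068 (62.9%) were in neither class, and missing the threshold does not show that they were equal to Veh. In all, 539 genes were called with the same sign against both other groups, where independent lists would share 55.3 and simulated lists of the same lengths shared 269 on average (244 to 293). The correlation over genes was 0.68 (0.51 simulated) and the covariance 0.0311 (0.00999 simulated), a difference of 0.0211. EV_antaNC and EV_anta483 shared 6 calls of the same sign against Veh and 8 of opposite sign (3.71 of the same sign expected for independent lists, 36.4 on average in simulated lists of the same lengths; r 0.33, 0.49 simulated; covariance 0.0114, 0.00957 simulated).

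Genes with a predicted miR-483-5p site were not called as a group. Of 11465 tested genes with a searched 3' UTR, 570 held a site. The difference of the median log2 fold changes between genes with and without a site was -0.0052 in EV_antaNC against Veh, 0.0063 in EV_anta483 against EV_antaNC and 0.0072 in EV_anta483 against Veh. Camera gave adjusted p = 0.880 for each comparison, and the differences ranked 31, 15 and 36 from the lowest among 60 words of the same composition. Of genes with a site, 7 were called higher and 1 lower in EV_antaNC against Veh, 35 and 53 in EV_anta483 against EV_antaNC, and 14 and 22 in EV_anta483 against Veh. Of genes without a site the counts were 87 and 23, 839 and 759, and 339 and 374. These counts were not tested against each other. UTRs with a site were longer, with a median of 2578.5 bases against 1294 without.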

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

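The offset for GC content and length and the fit of libraries numbered 2 and 3 were chosen after the data were seen. Genes changed in EV_antaNC against Veh numbered 118, and 335 without a filter on low counts, 182 with DESeq2, 51 and 49 on log2(FPKM + 1) and log2(FPKM + 0.1), 15 on log2(FPKM + 1) without a filter, 0 at a fold of at least 2 (edgeR, with 1561 genes at an unadjusted p under 0.05), and 180 with the 6 libraries compared alone. They numbered 43 to 184 with a library left out (lowest without Veh 3, highest without EV_anta483 1), and 53, 44, 71 and 73 without EV_antaNC 3, Veh 2, Veh 1 and EV_antaNC 2. In EV_anta483 against EV_antaNC the 1698 genes became 992 on log2(FPKM + 1) without a filter, 30 at a fold of at least 2, and 1005 to 1635 with a library left out (lowest without EV_anta483 2). In EV_anta483 against Veh the 754 genes became 296 and 17 under the same settings and 322 to 872 with a library left out (322, 361, 422 and 459 without Veh 2, EV_anta483 2, Veh 3 and EV_anta483 3). The 99 genes changed back became 227 without a filter on low counts, 47 and 44 on log2(FPKM + 1) and log2(FPKM + 0.1), 15 on log2(FPKM + 1) without a filter, 0 at a fold of at least 2, and 39 to 120 with a library left out (39, 41, 49, 61 and 62 without Veh 2, Veh 3, EV_antaNC 3, Veh 1 and EV_antaNC 2). A fold limit calls fewer genes by construction; for the other settings the cause was not tested. With the GC offset 58 of the 118, 1344 of the 1698 and 711 of the 754 genes remained called. The libraries numbered 2 and 3 alone gave 168, 1421 and 990 genes and 111 changed back. They kept 92 of the 118, 1210 of the 1698, 610 of the 754 and 76 of the 99. With the replicate number as a block the counts were 522, 2427, 1446 and 359 changed back, and with the block and the GC offset 520, 2404, 1409 and 346. The labels do not pair the samples by number, so the block stayed an alternative. Deviations of same-number pairs correlated at 0.0285 to 0.245 (median 0.0923), with 4 of 9 over 0.1. For other pairs the median was -0.0894 and the highest 0.0779. In all, 6 of 9 libraries correlated best with their own number, and the second principal component set the libraries numbered 1 apart. A batch shared by library number is therefore possible, and the counts without the block do not account for it. Lists changed numbered 9, 6 and 7, and 0, 0 and 0 with an estimated correlation and 4, 7 and 2 with fry; the cause was not tested. With the block the inflammation and NF-kappaB list in EV_anta483 against EV_antaNC (adjusted p = 0.0404) and the mitochondrial DNA transcripts in EV_anta483 against Veh (0.0339) also passed, and no list call was lost. Of 193 calls of named genes 0 reversed under any setting, and 193 held with RLE size factors or the block, 185 with library size alone, 174 with the GC offset, 147 of 158 with DESeq2, 149 of 186 on log2(FPKM + 1), 112 on log2(FPKM + 1) without a filter, and 149 to 180 with a library left out (lowest without Veh 2). Seed-site differences were not called under any setting. Depth limits low genes: in EV_anta483 against EV_antaNC the SE was 0.36 for Afp and 0.31 for Ttr, both under 2 CPM, and 0.04 for Lbp, at 855 CPM in EV_anta483.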

Other observations

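The tests of GC content on all genes changed back, on those that stayed so and on the sterol and acute phase genes, the tests of an antagomir without vesicles, of the share of hepatocyte-like cells and of repression through seed sites, the splits for genes changed back with EV_anta483 held, and the search over gene families were chosen only after the results they bear on were seen. Among 182 families of genes with a shared symbol stem and at least 8 tested members, 8 of 546 tests passed camera, in 5 families, and 0 passed with an estimated correlation. The Srsf family of splicing regulators stood higher in EV_antaNC than in Veh (4 of 10 genes called, Srsf1 at 0.48, Srsf5 at 0.34, Srsf2 at 0.33 and Srsf10 at 0.32; median 0.19, adjusted p = 9.67e-07; adjusted p = 0.841 with an estimated correlation). It stood lower in EV_anta483 than in EV_antaNC, with 8 of 10 genes called lower and a median of -0.29 (adjusted p = 4.86e-06; adjusted p = 0.841 with an estimated correlation). Ribosomal protein genes went the other way. Of 48 Rpl genes 6 were lower in EV_antaNC than in Veh (median -0.07, adjusted p = 1.49e-05) and 25 higher in EV_anta483 than in EV_antaNC (median 0.10, adjusted p = 9.67e-07). Of 41 Rps genes 2 were lower (median -0.08, adjusted p = 5.57e-05) and then 19 higher and 1 lower (median 0.11, adjusted p = 5.64e-05), and all 4 tests gave adjusted p = 0.924 with an estimated correlation. None of these directions turned with RLE factors, library size alone or the GC offset, although with library size alone 7 Srsf genes and 0 Rpl genes were called in EV_antaNC against Veh. The Zfp and Ccdc stems stood higher in EV_antaNC than in Veh by medians of 0.05 and 0.08 (adjusted p = 0.0376 and 0.0481; adjusted p = 0.924 for both with an estimated correlation), and Zfp was lost with the GC offset (adjusted p = 0.348). Many Rpl and Rps genes have near-identical copies and are uncertain.

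With 10 splits of 6 libraries into 3 and 3, no share under 0.05 could be reached. The real split called 118 genes in EV_antaNC against Veh (highest other 7), 1698 in EV_anta483 against EV_antaNC (highest other 0) and 754 in EV_anta483 against Veh (highest other 0), and 1 split, the real one, gave as many in each. For lists the real split gave 9, 6 and 7, the highest other 6, 8 and 5, and 1, 2 and 1 splits gave as many. For the absolute difference at seed sites the real split gave 0.00518, 0.00628 and 0.00722, the highest other 0.00681, 0.0103 and 0.00965, and 4, 5 and 2 splits gave as much. For genes changed back, 2 of 100 drawn assignments of the 9 libraries gave at least 99, the real one included, a share under 0.05. Only 4 of the other 99 gave any such gene, so this share says little about EV_antaNC against Veh. With EV_anta483 held, the real split of the Veh and EV_antaNC libraries gave 99 and the highest of the other 9 splits 4, and those 10 splits cannot give a share under 0.05. The other drawn assignment of at least 99 gave 419 and had the EV_anta483 libraries in the place of EV_antaNC, which points to a structure of the samples in which EV_anta483 stands apart.

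The 99 genes changed back, among them Luc7l3, Srsf1 and Arglu1, were set against the GC trend of the libraries and the temperature at harvest. The median log2 fold change against Veh over all 99 was taken in the direction of the call. It went from 0.27 to 0.21 with the GC and length trend removed (median SE per gene 0.05 for both). Of the 99, 51 stayed changed back. That count cannot decide whether the trend was the whole cause. The 99 were chosen as called genes, and the medians of the GC groups in EV_antaNC against Veh lay within 0.05 of 0. Removing a trend of that size could hardly leave none. The medians of the 99 show only that the fitted trend took away part of the change. The choice of called genes may have raised what was left. Those 51 were picked by that outcome in the same libraries, so they are no separate evidence. All 99 kept their sign, which says little given that choice and the small trend. The trend stays open as a cause, also for the other 48 genes. Their median went from 0.24 to 0.16 (median SE per gene 0.05 for both), 69.1% of its size. Of them 47 lost the call against Veh, at a smaller fold with an unchanged error. A difference in temperature at harvest could also act on splicing factors. The cold-induced genes Cirbp and Rbm3 gave a median of 0.0504 (median SE per gene 0.0588) and 6 heat shock genes -0.015 (median SE per gene 0.039). This leaves temperature open because the per-gene error of the cold-induced genes spans the limit set. An error of the median itself was not computed. An answer to the vesicles that depends on miR-483-5p stays among the open explanations, untested apart from these. Only EV_antaNC received the control antagomir, and no group received it without vesicles. An effect of that antagomir itself on these genes therefore cannot be told apart here.

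Cholesterol and fatty acid synthesis genes higher in EV_anta483 than in EV_antaNC numbered 29. All 29 stayed called with the GC trend removed and at least 22 with any library left out (22 without EV_antaNC 3 or EV_anta483 1). They were chosen as called in these libraries, so these counts say little. All tested members of the 2 lists, called or not, had medians of 0.25 (cholesterol) and 0.18 (fatty acid). With the trend removed these were 0.27 and 0.19, while the median of all genes shifted by 0.02. This argues against that trend as the cause. With any library left out, camera at the preset correlation still passed both lists (adjusted p up to 2.32e-09 and 0.00783). This argues against 1 library as the cause. An effect of the antagomir on the cells without the vesicles cannot be told apart from an effect through the vesicles, because 0 groups received the antagomir alone. A candidate explanation in which antagomir carried with the vesicles acts on sterol synthesis is therefore open.

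Acute phase genes lower in EV_anta483 than in EV_antaNC numbered 5 (Orm1, Lbp, Lcn2, Orm2 and Hpx). All 5 stayed called with the GC trend removed, and 4 without any 1 of the 6 EV_antaNC and EV_anta483 libraries, where Orm2 (EV_antaNC 3) or Hpx (the other 5) was lost. A smaller share of hepatocyte-like cells could lower them, but 6 of 11 tested hepatocyte identity genes lay above the median fall of -0.35 by more than 2 standard errors, among them Hnf4a at -0.16 (SE 0.08), Foxa2 at 0.06 (SE 0.07) and Nr1h4 at -0.02 (SE 0.04), which argues against it, although Alb and Ttr fell. A direct effect of the antagomir was not separated from one through the vesicles here either.

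A hypothesis was that miR-483-5p carried by the vesicles lowers genes with a seed site on average. The difference between genes with and without a site in EV_antaNC against Veh was -0.0052 (bootstrap SE 0.0063, 2000 resamples). It lies above -0.05 by more than 2 SE, but that bound was set after the difference was seen. Genes were resampled, not libraries, so the SE leaves out the spread between libraries. Other splits of these libraries gave absolute differences up to 0.00681. For these libraries the values argue against an average fall of 0.05 or more. A smaller fall, or one of a few targets, may still be present at a difference of -0.0052.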
